A study of Mus musculus with 12 samples.

How the data were processed

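Bulk RNA sequencing was analysed for bone marrow-derived macrophages (BMDMs), which are macrophages grown in culture from mouse bone marrow. The cells came from control mice (WT) or from mice with the R150X allele of Gpnmb (R150X), and were left untreated or given oxidised low-density lipoprotein (OxLDL). Macrophages that take up modified lipoprotein fill with lipid droplets and are called foam cells. The labels gave the strain of both genotypes as DBA/2 crossed and then backcrossed to C57BL/6. They gave no OxLDL dose or duration, no batch and no source (mouse, culture or pool) of a group's 3 libraries. Every p-value measures their spread, which may be technical. Markers of both sexes in each R150X library fit pooling. Total RNA was isolated with a Qiagen RNeasy Plus kit and libraries were made with the Hieff NGS Ultima Dual-mode kit, per the labels' protocols.

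The deposited table held raw counts per Ensembl gene for all 12 libraries, as whole numbers that summed to a different total in each library. FastQC, HISAT2, featureCounts and DESeq2 and the genome builds mm10 and GRCm38 were named, without versions, in the submitters' processing notes. The annotation release and the strand setting of the counting were not given in the sources used here, so reads from overlapping or antisense genes could not be told apart, and genes that share reads with near-identical copies were treated as uncertain. Total counts per library ran from 14838969 to 18222868, and the floor of 3 counts corresponded to 0.158 to 0.209 CPM (counts scaled to a common library total). The table listed 54532 genes, of which 29313 had at least 1 count. Symbols and GRCm38 coordinates came from the GENCODE annotation of that build, where 54409 identifiers matched. The 123 identifiers without a match held 0.0454% of all counts and stayed in the fits under their identifiers.

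Each column was assigned to a sample by its name. Replicates of each group were compared by a chi-square statistic of their counts over genes before they were averaged, and none agreed within sampling noise, so none was counted as a repeat deposit. Low-count genes were removed with edgeR's filterByExpr by group, which left 15338 genes. Libraries were scaled by trimmed mean of M-values (TMM), with factors from 0.969 to 1.05, and CPM values refer to these scaled library sizes. One model with a coefficient per group was fitted to all 12 libraries with edgeR version 4.0.16 under R 4.3.3, and 5 comparisons were tested with its quasi-likelihood test. These were R150X against WT in untreated cells, R150X against WT in OxLDL-treated cells, OxLDL against untreated in WT, OxLDL against untreated in R150X, and the interaction, which is the OxLDL response in R150X minus that in WT. A gene was counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and "rose" and "fell" are used only of genes that passed. Every adjusted p given for a gene comes from this test, every SE is that of the fitted log2 fold change, and every mean ± SD of CPM is over n = 3 libraries. The common biological coefficient of variation was 0.0608.

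Gene lists were tested with camera from limma version 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 18 pathway lists within a comparison, and 10 lists of other cell types and of RNA quality were adjusted separately. The pathway lists were LXR target genes, cholesterol biosynthesis, scavenger receptors and lipoprotein uptake, PPAR targets and lipid droplets, fatty acid beta-oxidation, the NRF2 antioxidant response, the lysosome and CLEAR network, inflammatory cytokines and NF-kB targets, the interferon response, alternative activation, lipid-associated macrophage genes, the integrated stress response (ATF4), ER chaperones, glycolysis and hypoxia, the cell cycle, adhesion and matrix remodelling, MHC class II antigen presentation, and macrophage identity. The other lists were markers of neutrophils, dendritic cells, T and NK cells, B cells, fibroblasts and stroma, erythroid cells, mast cells and basophils, and osteoclasts, the Y-linked genes with Xist, and the mitochondrially encoded mRNAs. Camera with a correlation estimated from the data and the self-contained test fry served as alternatives. Counts of members were taken over all genes tested and again adjusted over the list alone.

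The groups, the 5 comparisons, the lists, the tests, the rule for named genes and the main alternatives were chosen before the data were examined. The rule named Gpnmb, then the 6 genes with the highest and the 6 with the lowest log2 fold change among changed genes with a mean of at least 5 CPM in the higher group, an approved symbol other than a clone or Gm name and, except for the interaction, no overlap between the libraries of the 2 groups, which chance gives for 10% of genes with 3 libraries against 3. It also named up to 3 members of each list with the smallest adjusted p, and among members that did not pass only the 3 most highly expressed. Some genes that the rule named, often the third of a list, are left out for length. A gene with 0 counts in a group is given as a bound from 3 counts over the group, and a gene with 1 to 3 counts as a ratio with its 95% counting interval. These intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

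Fisher's exact test, two-sided, compared the share of changed genes within 20 Mb of Gpnmb on chromosome 6 with the rest of the genome. The OxLDL responses of the genotypes, which share no library, were compared by a total least squares slope through the origin. Alternatives were DESeq2 version 1.42.0, DESeq2's size factors in edgeR, no filter on low counts, a filter of at least 1 CPM in 3 libraries, a robust dispersion, a fit to only the groups compared, the replicate number as a block, a log2 fold change of at least 1, windows of 10 and 50 Mb, the exclusion of genes near Gpnmb, and the removal of each library in turn. Scaling by library size alone and the exclusion of genes on chromosomes X and Y were added after the data had been seen, as were 7 further gene lists given in the last part (markers of adipocytes, megakaryocyte and platelet genes, genes escaping X inactivation, cytosolic tRNA synthetases, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain and the proteasome), whose camera values were adjusted over these 7. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

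The tests were tried on simulated data, with counts for the real genes drawn from the real means and library sizes and 100 genes changed at each of 2 fold sizes. Over 10 simulated sets, the untreated genotype comparison recovered a mean of 63.8 of the 100 genes changed 1.5-fold and 83.0 of those changed 2-fold. The corresponding means were 65.5 and 78.9 for the genotype comparison with OxLDL, 65.8 and 80.5 for OxLDL in WT, 69.1 and 82.0 for OxLDL in R150X, and 51.1 and 72.7 for the interaction. Unchanged genes made up a mean of 5.59%, 5.66%, 5.18%, 6.87% and 6.99% of the calls in these comparisons, in that order, with single sets reaching 13.0% for OxLDL in R150X and 13.4% for the interaction. More than 1 set was simulated because the first set of the interaction had given that highest share. Camera called a list of 29 or 30 genes raised 1.5-fold in all 5 comparisons with either correlation, and 0 of 18 unchanged lists. As genes were drawn independently, effects of their correlation were untested. The slope was 0.798 for a true value of 0.8. The odds ratio near Gpnmb in the untreated genotype comparison was 20.3 for a true 21.5. In that comparison the true grouping called 140 genes and no other split more than 2.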

Results

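Gene expression was measured by RNA sequencing in 12 libraries of mouse BMDMs, 3 from each of 4 groups: untreated WT, untreated R150X, OxLDL-treated WT and OxLDL-treated R150X cells. The series asked how GPNMB, a transmembrane glycoprotein abundant in lipid-laden macrophages, affects the formation of foam cells. In a principal component analysis, component 1 held 57.3% of the variance and component 2 held 15.9%. Replicates differed by 2.40 to 5.14 units of chi-square per degree of freedom, except that replicate 1 of the untreated R150X group differed from replicates 2 and 3 by 10.2 and 11.1 units.

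Gpnmb was the mutated gene, and its level separated the genotypes in every library. The gene (ENSMUSG00000029816) lies on chromosome 6 from 49036546 to 49070929 on the plus strand of GRCm38. Untreated WT cells held 5330 ± 37.8 CPM of Gpnmb (SD, n = 3) and untreated R150X cells 385 ± 23.9 CPM, a log2 fold change of -3.79 (SE 0.0421, adjusted p = 1.03e-23). With OxLDL the level was 12508 ± 136 CPM in WT and 706 ± 16.3 CPM in R150X, a log2 fold change of -4.15 (SE 0.0427, adjusted p = 2.2e-24). OxLDL raised Gpnmb in both genotypes, by 1.23 on the log2 scale in WT and by 0.87 in R150X. The response in R150X was smaller by a log2 difference of -0.36 (SE 0.0535, adjusted p = 0.000152).

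**Figure D1:**
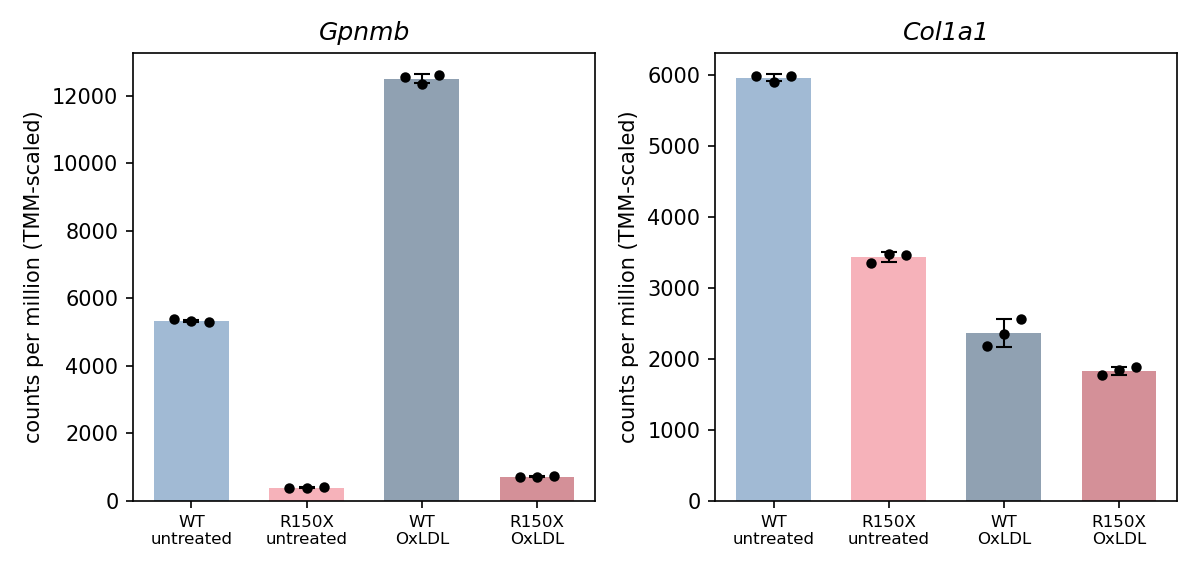
Level of Gpnmb (left) and of the collagen gene Col1a1 (right) in TMM-scaled CPM on linear axes, by group; bars give the mean, error bars the SD and points the 3 libraries. Gpnmb averaged 5330 and 12508 CPM in the WT groups against 385 and 706 CPM in the R150X groups, and Col1a1 fell with OxLDL from 5967 to 2365 CPM in WT.

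Xist, the RNA that silences an X chromosome in female cells, also separated the genotypes. It was present at 228 to 349 CPM in the 6 R150X libraries, at 0.590 to 2.75 CPM in untreated WT libraries and at 0 to 0.0695 CPM in OxLDL-treated WT libraries. The 4 Y-linked genes tested were detected in both genotypes and fell in R150X. Relative to WT, untreated R150X cells kept 65.1% of Ddx3y, 73.1% of Eif2s3y, 56.3% of Kdm5d and 57.3% of Uty, and with OxLDL they kept 60.8%, 63.0%, 61.2% and 55.9%. The sex of the mice was not given in the labels, and no genotype comparison given here separates the allele from this difference. Without genes on chromosomes X and Y, an exclusion chosen after the data had been seen, 4875 genes were called between untreated genotypes and 1936 with OxLDL, against 5056 and 1996 with all genes.

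**Figure D2:**
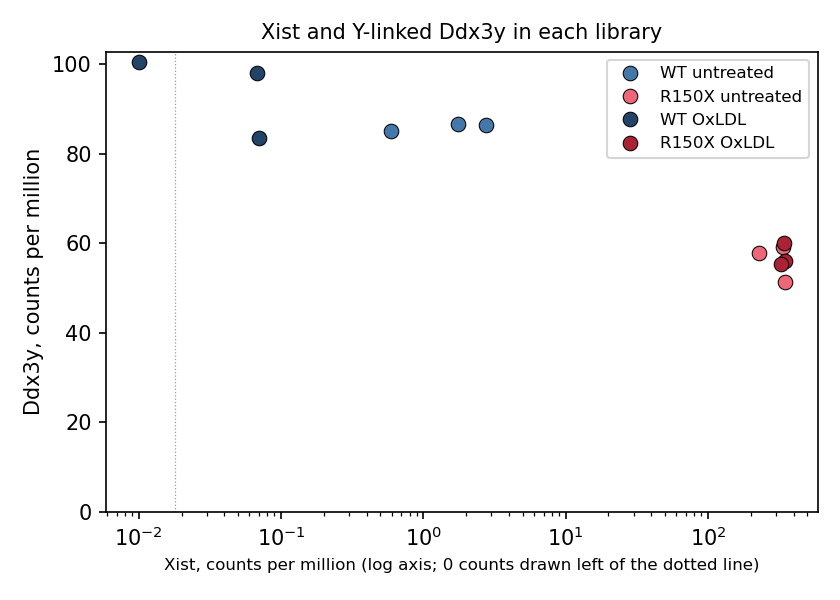
Xist (horizontal log axis) against the Y-linked gene Ddx3y (vertical linear axis) in TMM-scaled CPM, 1 point per library, coloured by group; the library with 0 Xist counts is drawn left of the dotted line. The 6 R150X libraries lie at 228 to 349 CPM of Xist, and mean Ddx3y is 86.1 and 94.0 CPM in the WT groups against 56.1 and 57.1 CPM in the R150X groups.

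The first comparison asked how untreated R150X macrophages differ from untreated WT macrophages. Genes of lysosomes, lipid storage, antioxidant defence and MHC class II were higher in R150X, and markers of neutrophils and stroma were lower. Cd36, a receptor for oxidised lipoprotein, rose from 1396 ± 30.2 to 2746 ± 112 CPM (log2 fold change 0.98, SE 0.0466, adjusted p = 2.51e-12). The lysosomal gene Psap rose from 8638 ± 51.0 to 12734 ± 613 CPM and lipoprotein lipase (Lpl) from 3980 ± 113 to 6289 ± 135 CPM. Cd74, the invariant chain that accompanies MHC class II, rose from 145 ± 5.46 to 326 ± 25.9 CPM.

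Among PPAR targets and lipid droplet genes, 12 of 20 rose and 3 fell (camera adjusted p = 7.78e-10). Mgll, which encodes monoacylglycerol lipase, had a log2 fold change of 1.75, and Plin2, a protein coat of lipid droplets, 0.66. In the lysosome and CLEAR network, 27 of 38 rose and 1 fell (adjusted p = 5.36e-13), with the proton pump subunit Atp6v1b2 at 0.67 and cathepsin D (Ctsd) at 0.55. Of the NRF2 antioxidant genes, 20 of 23 rose and 1 fell (adjusted p = 1.82e-11), among them the redox enzymes Srxn1 at 0.65 and Prdx1 at 0.68 and the pentose phosphate enzyme Pgd at 0.50. Lipid-associated macrophage genes rose in 13 of 18 cases and fell in 4 (adjusted p = 7.81e-10), with Anxa1 at 0.75 and the actin-capping gene Capg at 0.79. The lectin gene Clec7a stood at 0.97, and its annotation as a polymorphic pseudogene makes its count uncertain. Cholesterol biosynthesis rose in 13 of 24 genes (8 without WT replicate 2) and fell in 0 (adjusted p = 0.00112), led by Insig1 at 0.43 and Sqle at 0.41. Beta-oxidation genes rose in 11 of 18 cases (6 without WT replicate 2) and fell in 0, with Hadh at 0.42 and Hadha at 0.22, and this call (adjusted p = 0.00293) was lost at an adjusted p = 0.13 with an estimated correlation.

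Of 26 cytokine and NF-kB genes, 13 rose and 4 fell (camera adjusted p = 0.000359). The neutrophil-attracting chemokines Cxcl3 and Cxcl2 had log2 fold changes of 2.27 and 2.16, and interleukin-1 beta (Il1b) rose from 116 ± 3.60 to 245 ± 9.30 CPM. MHC class II genes rose in 7 of 10 cases and fell in 0 (adjusted p = 4.53e-08), with Cd74 at 1.17 and H2-Eb1 at 1.11, where related H2 genes can share reads. Interferon genes rose in 9 of 32 cases and fell in 2 without a list call (adjusted p = 0.115, and called at an adjusted p = 0.0408 without a filter on low counts), Gbp2 being at 0.63 and Cmpk2 at 0.45. Alternative activation genes fell in 6 of 13 cases and rose in 3 (adjusted p = 0.00243), with the chitinase-like gene Chil3 at -1.93 and the interleukin-4 receptor Il4ra at -0.56. Chil3 has close relatives with which it can share reads.

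Stress and glycolysis genes were mostly lower in untreated R150X cells, with calls that depended on the assumed correlation. ATF4 targets fell in 12 of 21 cases and rose in 6 (camera adjusted p = 0.0404, and adjusted p = 0.372 with an estimated correlation). The call was also lost without WT replicate 3 (adjusted p = 0.0838) or R150X replicate 2 (adjusted p = 0.166) or 3 (adjusted p = 0.102). The mitochondrial folate enzyme Aldh1l2 was at -1.15, Ddit4 at -0.59 and Atf3 at 0.56. Glycolysis and hypoxia genes fell in 12 of 22 cases and rose in 2 (adjusted p = 0.00124, and adjusted p = 0.13 with an estimated correlation), including the mitophagy receptor Bnip3 at -0.71 and Pfkfb3 at -0.41. Adhesion and matrix genes went both ways, 7 of 26 rising and 9 falling (adjusted p = 0.632, median -0.02 but mean 0.01). The proteases Mmp9 and Mmp12 were at 1.24 and 1.00, and the matrix protein Thbs1 at -0.72.

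The remaining pathway lists were not called in untreated cells. LXR targets, which serve cholesterol efflux, rose in 6 of 13 cases and fell in 3 (adjusted p = 0.395), with the transporter Abcg1 at 0.32, the receptor Nr1h3 at 0.39 and Pltp at -0.31. The most highly expressed of them, Apoe and Abca1, did not pass at 0.10 (adjusted p = 0.307) and 0.07 (adjusted p = 0.451). Scavenger receptor genes rose in 4 of 15 cases and fell in 3 (adjusted p = 0.514), and Cd68 was at 0.27 and Vldlr at -0.67. ER chaperones rose in 6 of 19 cases (3 without WT replicate 2, 2 without WT replicate 3 or R150X replicate 1) and fell in 2 (adjusted p = 0.514), with Sdf2l1 at 0.47 and Pdia4 at -0.44. Cell cycle genes rose in 3 of 30 cases and fell in 2 (adjusted p = 0.996), Pcna being at 0.58, E2f1 at 0.34 and Mki67 at -0.55, and camera's direction was up while median and mean were -0.02 and -0.0029. Macrophage identity genes rose in 7 of 15 cases and fell in 4 (adjusted p = 0.632, median 0.13 but mean -0.03), with Cd14 at 0.77, Ly6c2 at -1.20 and Cx3cr1 at -0.79.

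Among markers of other cells, neutrophil markers fell in 11 of 12 cases and rose in 0 (camera adjusted p = 1.79e-18), with the granule genes Ngp at -1.32 and S100a9 at -1.28. Fibroblast and stromal markers fell in 9 of 12 cases and rose in 2 (adjusted p = 1.85e-09), and the collagen genes Col1a1 at 5967 ± 48.8 CPM in WT against 3432 ± 72.0 CPM in R150X, Col1a2 at -0.56 and Col3a1 at -0.57 were among them. Osteoclast markers rose in 3 of 6 cases and fell in 2 (adjusted p = 0.0793), with the fusion receptor Dcstamp at 1.66 and cathepsin K (Ctsk) at 0.68. B cell markers rose in 1 of 4 cases (Blnk at 0.55, list adjusted p = 0.579), and 2 fell without R150X replicate 2. Dendritic cell markers rose in 1 of 6 cases (Batf3 at 0.42) and fell in 1 (Tcf4 at -0.37, list adjusted p = 0.911). None of 4 T and NK markers (adjusted p = 0.931) and none of 4 mast cell and basophil markers (adjusted p = 0.462) passed the edgeR test, also when adjusted over the list alone. The 1 erythroid marker tested, Epor, was lowly expressed at 1.57 CPM in WT and 2.72 CPM in R150X, a rise whose call was lost without R150X replicate 1 (adjusted p = 0.0599). Mitochondrial mRNAs rose in 5 of 12 cases (adjusted p = 0.264), in 2 by library size alone, 3 without WT replicate 1, 2 without R150X replicate 1 or 3 and 1 without WT replicate 2 or 3 or R150X replicate 2. The list of Y-linked genes with Xist moved both ways, 1 of 5 up and 4 down (adjusted p = 0.931, median -0.62 but mean 0.96).

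The largest differences between untreated genotypes are given for genes with at least 5 CPM in the higher group and a name other than a clone or Gm number. Higher in R150X, beside Xist at 7.48, were the proton pump subunit Atp6v0e2 at 4.79 and the processed pseudogene Rps3a2 at 4.26, whose count is uncertain because it can share reads with Rps3a1 and other copies, and Tmem178 at 2.44. The interferon-inducible gene Ifi202b, on chromosome 1 from 173962568, averaged 32.2 ± 1.03 CPM in WT and had 0 counts in R150X, so that it was at least 547-fold lower. It belongs to a family of near-identical genes, so its count is uncertain. Sox11 at -1.93, the copper chaperone Cox17 at -1.91 and the imprinted RNA Meg3 at -1.76 were also lower. These genes were lowly expressed, with means of 5.86, 6.22 and 8.13 CPM in WT.

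In total, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 5056 of 15338 genes between untreated genotypes, 2780 higher and 2276 lower in R150X, of which 179 and 305 differed at least 2-fold. Scaled by library size alone, 5120 genes were called and 36.1% of them were higher, against 55.0% with TMM scaling, so the balance of directions depended on scaling. Under that scaling the counts of LXR targets that rose and fell became 3 and 3, of scavenger genes 3 and 5, of ER chaperones 1 and 3, of cell cycle genes 2 and 4, of beta-oxidation genes 7 and 0 and of B cell markers 1 and 2. Of lysosomal genes 3 fell and of interferon genes 5. The medians of interferon genes (0.03), ER chaperones (0.07) and T and NK markers (0.02) turned to -0.04, -0.0032 and -0.05. Adjusted over the list alone, counts differed for cholesterol biosynthesis (15 rose), beta-oxidation (13 rose), the lysosome (28 rose, 2 fell), cytokines (14 rose, 5 fell), ATF4 targets (14 fell), adhesion (10 fell), MHC class II (1 fell), macrophage identity (8 rose), neutrophil markers (12 fell) and B cell markers (2 fell). Without replicate 1 of the untreated R150X group, 4174 genes were called.

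Calls near Gpnmb were somewhat more frequent than elsewhere. Within 20 Mb of Gpnmb, from 29036546 to 69070929 on chromosome 6, 86 of 214 tested genes (40.2%) were called between untreated genotypes against 32.9% elsewhere, an odds ratio of 1.37 (95% interval 1.03 to 1.82, Fisher's exact p = 0.0278). Atp6v0e2, at 48537615, lies in this window. This call was lost with DESeq2, at an odds ratio of 1.08 (Fisher's exact p = 0.546), and without any of 5 of the 6 libraries, which gave 1.34 and 1.28 without WT replicates 1 and 3 and 1.30, 1.27 and 1.14 without R150X replicates 1, 2 and 3. With OxLDL, 36 of the 214 genes (16.8%) were called against 13.0% elsewhere, an odds ratio of 1.36 (0.919 to 1.96, exact p = 0.101).

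The comparison of genotypes under OxLDL asked how R150X foam cells differ from WT foam cells. Markers of macrophage identity, adhesion genes and neutrophil markers were lower in R150X, and lipid droplet genes and 3 genes typical of adipocytes were higher. Osteopontin (Spp1), a secreted matrix protein, fell from 11780 ± 683 CPM in WT to 6289 ± 313 CPM in R150X (log2 fold change -0.91, SE 0.0408, adjusted p = 1.12e-12). Cd36 was 4377 ± 295 CPM in WT and 5445 ± 260 CPM in R150X (0.32, SE 0.0461, adjusted p = 4.85e-05).

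Among PPAR targets and lipid droplet genes 7 of 20 rose and 3 fell (camera adjusted p = 0.000466). Mgll at 1.30 and Plin4 at 1.21 rose, and the fatty acid carrier Fabp5 was at -0.32. The lipid droplet gene Plin1, the hormone gene Adipoq and the carbonic anhydrase Car3, all typical of adipocytes, were at 11.8, 15.8 and 13.1 CPM in R150X against 0.978, 1.58 and 0.338 CPM in WT. Lysosomal genes rose in 13 of 38 cases (8 without WT replicate 2) and fell in 3 (adjusted p = 0.0053, and adjusted p = 0.304 with an estimated correlation), with the autophagy receptor Sqstm1 at 0.38 and Ctsk at 0.46, while Ctsb did not pass at 0.05 (adjusted p = 0.194). LXR targets rose in 1 of 13 cases and fell in 5 (adjusted p = 0.0528), where the desaturase Scd1 was at 1.52, Pltp at -0.62 and Mylip at -0.75. That list was called with replicate as a block (adjusted p = 0.0447), with no filter on low counts (adjusted p = 0.00382), and without WT_OxLDL replicate 2 (adjusted p = 0.0315) or R150X_OxLDL replicate 3 (adjusted p = 0.0347). Scavenger genes rose in 3 of 15 cases (1 without WT replicate 1) and fell in 2 (adjusted p = 0.268), with Cxcl16 at -0.95 and Vldlr at -0.72. Cholesterol biosynthesis rose in 4 of 24 cases (1 without WT replicate 1, 2 without WT replicate 2 or 3 or R150X replicate 2 or 3) and fell in 1 (adjusted p = 0.827, median 0.01 but mean -0.0030), Srebf2 being at 0.27. Beta-oxidation genes fell in 2 of 18 cases, Ucp2 at -0.48 and Cpt1a at -0.30 (list adjusted p = 0.99, test down with median 0.04 and mean 0.02). NRF2 genes rose in 5 of 23 cases (3 without R150X replicate 3) and fell in 2 (adjusted p = 0.871, median 0.01 but mean -0.0025), with the cystine transporter Slc7a11 at 0.51 and Gsr at -0.41.

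ATF4 targets were mostly higher in R150X under OxLDL, 11 of 21 rising and 3 falling (camera adjusted p = 0.000286, and adjusted p = 0.129 with an estimated correlation). Atf4 itself was at 0.56, the cytokine Gdf15 at 0.75 and Ddit4 at -0.82. Glycolysis and hypoxia genes fell in 9 of 22 cases (4 without WT replicate 3 or R150X replicate 2) and rose in 2 (adjusted p = 0.000466, and adjusted p = 0.129 with an estimated correlation), including the lactate exporter Slc16a3 at -0.60 and Bnip3 at -0.60. Pkm and Aldoa did not pass at -0.08 (adjusted p = 0.215) and 0.03 (adjusted p = 0.74). ER chaperones rose in 1 of 19 cases (0 without WT replicate 1 or 2 or R150X replicate 1 or 3) and fell in 2 (adjusted p = 0.968), with Pdia4 at -0.34 and Edem1 at -0.22. Among cell cycle genes 1 of 30 rose (0 without WT replicate 2 or 3 or R150X replicate 1) and 0 fell (adjusted p = 0.781), and Mki67 did not pass at 0.06 (adjusted p = 0.739).

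Macrophage identity genes fell in 9 of 15 cases and rose in 0 (camera adjusted p = 1.93e-06), with the Fc receptor Fcgr1 at -0.64 and the monocyte marker Ly6c2 at -1.86. Adgre1 did not pass at -0.12 (adjusted p = 0.0565). Adhesion and matrix genes fell in 13 of 26 cases and rose in 5 (3 rose without WT replicate 2, adjusted p = 0.000192), with Thbs1 at -0.67, Mmp13 at -0.61 and the integrin Itgb3 at 1.39. MHC class II genes fell in 5 of 10 cases (2 without WT replicate 1 or 3, 3 without WT replicate 2 or any R150X replicate) and rose in 0 (adjusted p = 0.0194, and adjusted p = 0.178 with an estimated correlation), led by H2-DMa at -0.39. Alternative activation fell in 3 of 13 cases and rose in 1 (adjusted p = 0.0194, and adjusted p = 0.121 with an estimated correlation and 0.357 without a filter on low counts), with Chil3 at -2.18 and Il4ra at -0.64. Cytokine and NF-kB genes rose in 5 of 26 cases and fell in 8 (5 fell without WT replicate 1 or R150X replicate 2, adjusted p = 0.43), where the interleukin-1 antagonist Il1rn was at 0.76, Ccl3 at 0.74 and Ccl7 at -1.04. Interferon genes rose in 4 of 32 cases and fell in 3 (1 fell without WT replicate 1 or 3 or R150X replicate 2 or 3, adjusted p = 0.43), with Stat2 at -0.29 and Cmpk2 at 0.54. Lipid-associated macrophage genes rose in 7 of 18 cases and fell in 2 (adjusted p = 0.968, median 0.09 but mean -0.08 and test down), with Anxa1 at 0.30 and, beside Spp1, the receptor kinase Axl at -0.67.

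Neutrophil markers were again lower, 10 of 12 falling (camera adjusted p = 9.84e-43), with Ngp at -2.05 and myeloperoxidase (Mpo) at -2.88. Stromal markers fell in 5 of 12 cases and rose in 1 (adjusted p = 0.236), where the chemokine Cxcl12 rose from 770 ± 14.2 to 1437 ± 20.6 CPM, decorin (Dcn) was at -1.03, Acta2 at -0.38, and Sparc did not pass at 0.06 (adjusted p = 0.327). B cell markers rose in 1 of 4 cases (Ebf1 at 0.45, list adjusted p = 0.794), dendritic markers fell in 1 of 6 (Tcf4 at -0.23, adjusted p = 0.932), and osteoclast markers rose in 1 of 6 (Ctsk) and fell in 1 (adjusted p = 0.841). No T and NK marker (adjusted p = 0.861), mast cell marker (adjusted p = 0.841) or erythroid marker passed the edgeR test. One of 12 mitochondrial mRNAs, mt-Co1, fell (list adjusted p = 0.675). That call was lost by library size alone (adjusted p = 0.0798), with DESeq2 (adjusted p = 0.0704) and without WT replicate 1 (adjusted p = 0.215) or 2 (adjusted p = 0.167) or R150X replicate 2 (adjusted p = 0.127) or 3 (adjusted p = 0.244). Without WT replicate 3, 3 fell. The Y-linked list with Xist had 4 of 5 down and 1 up (adjusted p = 0.932, median -0.71 but mean 1.95).

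Under OxLDL, edgeR called 1996 genes between genotypes, 935 higher and 1061 lower in R150X, with 171 and 191 at least 2-fold. By the limits used for untreated cells, Atp6v0e2 at 6.54 and Rps3a2 at 3.75 were among the highest, as were Plin1, Adipoq and Car3 at 3.58, 3.32 and 5.26. Ifi202b had 0 counts in R150X and was at least 231-fold lower, and Xist, with 2 counts in WT, was higher in R150X by a ratio between 2115 and 63096. Between the genotype comparisons, 577 genes were higher in R150X in both treatments against 169 for independent lists, 667 were lower in both against 157, and 97 went opposite ways. Adjusted over the list alone, lists whose counts moved were LXR targets (2 rose, 7 fell), PPAR targets (8 rose), the lysosome (16 rose), cytokines (9 fell), interferon (6 rose), scavenger (3 fell), NRF2 (6 rose, 4 fell), alternative activation (2 rose), lipid-associated genes (9 rose, 4 fell), ATF4 (5 fell), glycolysis (13 fell), adhesion (14 fell), MHC class II (6 fell), macrophage identity (1 rose, 10 fell), neutrophil (11 fell), dendritic (1 rose, 2 fell), mast cell (1 fell) and mitochondrial (0 fell). Scaled by library size alone, the median of alternative activation turned from -0.01 to 0.0023. Of the 8 pathway lists called here, 3 stayed called with an estimated correlation.

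The next comparison asked what OxLDL does to WT macrophages. Interferon and inflammatory genes fell steeply, cholesterol synthesis fell, and genes of lipid storage and lysosomes rose. The chemokine Cxcl9 went from 133 ± 3.28 CPM to 1 count in all 3 treated libraries, a decrease by a ratio between 1077 and 237080. Saa3, an acute-phase protein, fell from 1910 ± 97.7 to 1.09 ± 0.0832 CPM, and Acod1, which makes itaconate, from 332 ± 3.37 to 0.315 ± 0.114 CPM. Cd36 rose from 1396 ± 30.2 to 4377 ± 295 CPM (log2 fold change 1.65, SE 0.0473, adjusted p = 3.52e-17). Plin2 rose from 395 ± 7.10 to 1262 ± 32.4 CPM and Psap from 8638 ± 51.0 to 18595 ± 101 CPM.

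All 32 interferon response genes fell in WT (camera adjusted p = 5.14e-213, median -3.70), among them Irf7 at -4.93 and Ifit1 at -5.77, and Cxcl9 lies below that median at either end of its counting interval. Cytokine and NF-kB genes fell in 25 of 26 cases and rose in 0 (adjusted p = 1.59e-47), with Ccl5 at -7.65 and Il1b at -5.53. Cholesterol biosynthesis fell in 20 of 24 cases and rose in 0 (adjusted p = 2.24e-23), with Cyp51 at -1.66. LXR targets rose in 9 of 13 cases and fell in 4 (adjusted p = 0.00617), with Mylip at 1.19, Abcg1 at 0.85 and the desaturase Scd2 at -0.86. PPAR and lipid droplet genes rose in 14 of 20 cases and fell in 4 (2 fell without WT_untreated replicate 3 or WT_OxLDL replicate 1, adjusted p = 1.79e-10), with Plin2 at 1.68 and Mgll at 1.67. Beta-oxidation genes rose in 15 of 18 cases and fell in 0 (adjusted p = 2.98e-06), led by the carnitine transferase Cpt1a at 1.15 and Ucp2 at 0.59. NRF2 genes rose in 19 of 23 cases and fell in 2 (adjusted p = 1.85e-14), with catalase (Cat) at 1.56 and Gstm1 at 1.54. Lysosomal genes rose in 34 of 38 cases and fell in 0 (adjusted p = 2.28e-16), with Psap at 1.11 and Ctsb at 0.80. Lipid-associated macrophage genes rose in 15 of 18 cases and fell in 2 (adjusted p = 1.11e-06), with the growth factor Igf1 at 1.19 and the lipid receptor Trem2 at 1.03.

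Macrophage identity genes fell in 8 of 15 cases and rose in 5 in WT (camera adjusted p = 0.000197), with Adgre1 falling from 2727 ± 41.1 to 833 ± 15.9 CPM, Cx3cr1 at -3.13 and Ly6c2 at -3.62. Cell cycle genes fell in 27 of 30 cases and rose in 1 (adjusted p = 2.06e-05), with Top2a at -0.78 and Mcm5 at -1.03. Scavenger genes rose in 5 of 15 cases and fell in 6 (adjusted p = 0.187, median 0.0030 but mean -0.78), Cd68 being at 0.79 and Marco at -9.51. Alternative activation fell in 6 of 13 cases and rose in 4 (adjusted p = 0.134), with Chil3 at -1.92 and Il4ra at -0.81. ATF4 targets fell in 14 of 21 cases and rose in 5 (adjusted p = 0.0145, and adjusted p = 0.223 with an estimated correlation), including the amino acid transporter Slc7a5 at -1.57, Aldh1l2 at -1.51 and Atf3 at 0.72. Glycolysis and hypoxia fell in 13 of 22 cases and rose in 1 (adjusted p = 0.00335, and adjusted p = 0.149 with an estimated correlation), with Ndrg1 at -1.93 and Pfkfb3 at -0.89. ER chaperones fell in 11 of 19 cases and rose in 1 (adjusted p = 0.0896, and called at an adjusted p = 0.000342 without a filter on low counts and 0.0218 by library size alone), with Herpud1 at -0.69 and Hspa5 at -0.51. Adhesion genes rose in 11 of 26 cases and fell in 12 (adjusted p = 0.0896, called at an adjusted p = 0.0288 by library size alone, median 0.02 but mean -0.15), with Mmp12 at 1.12, Mmp9 at -1.64 and Timp3 at -2.80. MHC class II genes rose in 5 of 10 cases and fell in 3 (adjusted p = 0.72), with H2-DMa at 0.60, Cd86 at 0.65 and Cd74 at -0.67.

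Stromal markers fell with OxLDL in the WT libraries, 8 of 12 falling and 0 rising (camera adjusted p = 2.36e-13), with periostin (Postn) at -2.33 and Sparc at -1.23. Neutrophil markers fell in 7 of 12 cases and rose in 1 (adjusted p = 4.38e-12), with Lcn2 at -3.69 and Ngp at -1.77. All 12 mitochondrial mRNAs tested rose (adjusted p = 1.28e-05, and adjusted p = 0.24 with an estimated correlation), with mt-Cytb at 0.82 and mt-Nd4 at 0.64. Their share of counts was 1.35% to 1.42% in untreated and 1.75% to 2.02% in OxLDL-treated WT libraries. Osteoclast markers rose in 3 of 6 cases (1 without WT_untreated or WT_OxLDL replicate 1) and fell in 2 (1 on leaving out any of the libraries, adjusted p = 0.833), with Atp6v0d2 at 1.09 and Acp5 at -1.97. Mast cell and basophil markers fell in 3 of 4 cases (Kit at -0.86, list adjusted p = 0.41), B cell markers in 3 of 4 (1 without WT_untreated replicate 1, Ebf1 at -0.32, adjusted p = 0.712) and dendritic markers in 2 of 6 (Tcf4 at -0.36, adjusted p = 0.686). The T and NK list rose in 1 of 4 cases (Cd4, also expressed by macrophages, at 0.71, adjusted p = 0.613). Epor, the 1 erythroid marker tested, was at 1.19 on low counts. Xist went from 95 to 2 counts, a ratio between 10.3 and 319, and among Y-linked genes Eif2s3y rose by 0.27, a call lost by library size alone (0.15, adjusted p = 0.0644; list adjusted p = 0.989, median 0.13 but mean -0.91).

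In WT, edgeR called 7025 genes with OxLDL, 3481 higher and 3544 lower, but 351 higher and 1104 lower at 2-fold or more. Scaled by library size alone, 31.6% of 7102 calls were higher, against 49.6% with TMM, and the median of all genes moved by -0.11 on the log2 scale. That scaling gave 29 rising lysosomal genes, 3 rising and 4 falling MHC class II genes, 3 rising ATF4 targets, and 1 rising and 2 falling osteoclast markers. It turned the medians of adhesion (0.02), MHC class II (0.07), scavenger (0.0030) and osteoclast genes (0.0024) to -0.09, -0.04, -0.11 and -0.11. By the limits given above, the highest genes were the platelet chemokine Ppbp at 3.26, Gsta3 at 2.68, Ear2 at 2.46, the integrin Itgad at 2.45, angiotensinogen (Agt) at 2.39 and Ccdc148 at 2.21. Slc13a3, an itaconate and succinate transporter, stood at -9.32, and Ifi213 went from 1098 counts to 1, a ratio between 158 and 34818. Ear2 and Ifi213 have near-identical family members. Adjusted over the list alone, counts moved for PPAR targets (15 rose), beta-oxidation (17 rose), ER chaperones (2 rose), glycolysis (2 rose), the cell cycle (28 fell), T and NK markers (2 rose) and stromal markers (1 rose).

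In R150X cells OxLDL again lowered interferon, inflammatory and cholesterol synthesis genes and raised genes of lipid storage and lysosomes. Saa3 fell from 2156 ± 393 to 0.978 ± 0.329 CPM, Acod1 from 641 ± 9.45 to 0.605 ± 0.129 CPM and Cxcl9 from 163 ± 1.90 to 0.145 ± 0.203 CPM. Cd36 rose from 2746 ± 112 to 5445 ± 260 CPM (log2 fold change 0.99, SE 0.0465, adjusted p = 1.56e-13), Plin2 from 624 ± 9.87 to 1405 ± 48.6 CPM and Psap from 12734 ± 613 to 20497 ± 192 CPM. Genes typical of adipocytes were highest among genes of at least 5 CPM, with Plin1 at 4.68 and Car3 at 4.08.

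All 32 interferon genes fell in R150X as well (camera adjusted p = 4.17e-254), with Gbp2 at -4.38 and Ifit1 at -5.72. Of 26 cytokine genes 25 fell and 0 rose (adjusted p = 7.92e-70), with Il1b at -7.81 and Ccl5 at -7.96. Cholesterol biosynthesis fell in 22 of 24 cases and rose in 0 (adjusted p = 3.13e-35), with Cyp51 at -2.04. LXR targets rose in 7 of 13 cases and fell in 3 without a list call (adjusted p = 0.167, and called at an adjusted p = 0.0137 without a filter on low counts), Mylip being at 0.74, Scd2 at -1.07 and Nr1h3 at -0.72. PPAR and lipid droplet genes rose in 14 of 20 cases and fell in 4 (adjusted p = 2.96e-06), with Plin2 at 1.17, Mgll at 1.22 and the acyl-CoA synthetase Acsl1 at -1.66. Beta-oxidation rose in 12 of 18 cases and fell in 0 (adjusted p = 0.00191, and adjusted p = 0.0976 with an estimated correlation), led by Cpt1a at 0.86. NRF2 genes rose in 14 of 23 cases and fell in 4 (adjusted p = 4.13e-05), with Cat at 1.23 and Gstm1 at 1.42. Lysosomal genes rose in 27 of 38 cases and fell in 1 (adjusted p = 2.83e-08), with the acid lipase Lipa at 0.82 and Psap at 0.69. Lipid-associated macrophage genes rose in 8 of 18 cases (5 without R150X_untreated replicate 2 or R150X_OxLDL replicate 3) and fell in 3 (adjusted p = 0.161, called at an adjusted p = 0.0443 without R150X_untreated replicate 1, median 0.08 but mean -0.06), with Igf1 at 0.79, Trem2 at 0.68 and Cst7 at -3.26.

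Macrophage identity genes fell in 10 of 15 cases and rose in 5 (camera adjusted p = 4.59e-11), with Adgre1 at -1.85 and Cd14 at -2.24. MHC class II fell in 5 of 10 cases and rose in 2 (adjusted p = 9.35e-05), with Cd74 at -2.06 and H2-Aa at -1.74. Cell cycle genes fell in 28 of 30 cases and rose in 0 (adjusted p = 2.64e-05), with Mcm5 at -0.998 and Top2a at -0.66. Adhesion genes fell in 14 of 26 cases and rose in 9 (adjusted p = 9.35e-05), with Mmp9 at -2.93 and Timp3 at -2.74. Scavenger genes rose in 5 of 15 cases and fell in 5 (adjusted p = 0.0153, and adjusted p = 0.067 with an estimated correlation and 0.531 without a filter on low counts), Marco being at -8.86 and Cxcl16 at -1.62. ER chaperones fell in 12 of 19 cases and rose in 3 (5 rose without R150X_untreated replicate 1, adjusted p = 0.0292, and adjusted p = 0.234 with an estimated correlation), with Herpud1 at -0.72 and Hspa5 at -0.52. Glycolysis fell in 15 of 22 cases and rose in 2 (adjusted p = 0.00443, and adjusted p = 0.153 with an estimated correlation), with Ndrg1 at -1.74 and Hk2 at -0.56. ATF4 targets rose in 13 of 21 cases and fell in 6 (adjusted p = 0.651, median 0.20 but mean -0.04), with Atf5 at 1.11, Slc7a5 at -1.16 and Nupr1 at -1.36. Alternative activation rose in 4 of 13 cases and fell in 4 (adjusted p = 0.326), with the mannose receptor Mrc1 at 0.74, Chil3 at -2.17 and Il4ra at -0.90.

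Stromal markers fell in 9 of 12 cases and rose in 1 (camera adjusted p = 4.59e-07), with Postn at -1.77 and Sparc at -0.85. Neutrophil markers fell in 9 of 12 and rose in 0 (adjusted p = 1.22e-16), with Lcn2 at -4.73 and Ngp at -2.50. Mitochondrial mRNAs rose in 9 of 12 cases (adjusted p = 0.00212, and adjusted p = 0.414 with an estimated correlation), with mt-Cytb at 0.68 and mt-Nd4 at 0.47, and their share was 1.33% to 1.43% in untreated and 1.69% to 1.92% in OxLDL-treated R150X libraries. Osteoclast markers rose in 2 of 6 cases and fell in 2 (adjusted p = 0.351), with Atp6v0d2 at 0.66, Acp5 at -1.81 and Dcstamp at -1.52. Dendritic markers rose in 1 of 6 cases and fell in 4 (2 without R150X_untreated replicate 1 or R150X_OxLDL replicate 1 or 2, Tcf4 at -0.23, adjusted p = 0.573). B cell markers rose in 1 of 4 (Ebf1 at 0.34) and fell in 1 (Blnk at -0.70, adjusted p = 0.573). T and NK markers rose in 1 of 4 (Cd4 at 0.92, adjusted p = 0.573), and mast cell markers fell in 2 of 4 (Kit at -0.48, adjusted p = 0.536). Epor rose by 0.52 on low counts, a call lost with DESeq2 (adjusted p = 0.111), no filter (adjusted p = 0.0738) and only the groups compared (adjusted p = 0.0647) and without untreated R150X replicates 2 or 3 or any OxLDL-treated R150X replicate (adjusted p of 0.0598 to 0.209). Of the Y-linked list, 1 of 5 rose (0 without R150X_untreated replicate 1 or R150X_OxLDL replicate 1 or 2, adjusted p = 0.573), and Xist and Ddx3y did not pass at 0.16 (adjusted p = 0.328) and 0.03 (adjusted p = 0.789).

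In R150X, edgeR called 5983 genes with OxLDL, 2826 higher and 3157 lower, with 249 higher and 912 lower at 2-fold or more. Without replicate 1 of the untreated R150X group, 5866 were called. Agt at 2.46, Itgad at 2.34 and the lipase inhibitor G0s2 at 2.31 were among the highest, Slc13a3 was at -9.19, and Tarm1 went from 621 counts to 1, a ratio between 109 and 24039. Adjusted over the list alone, counts moved for LXR targets (8 rose), scavenger (6 fell), NRF2 (5 fell), lipid-associated genes (4 fell), ATF4 (14 rose), ER chaperones (4 rose), glycolysis (16 fell), the cell cycle (29 fell), stromal markers (11 fell) and mast cell markers (3 fell). Between the genotypes, whose OxLDL comparisons share no library, 2038 genes rose in both against 641 for independent lists, 2362 fell in both against 729, and 100 went opposite ways. Over genes called in at least 1 genotype the slope of R150X on WT was 0.963 (jackknife SE 0.0686 over 12 libraries).

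**Figure D3:**
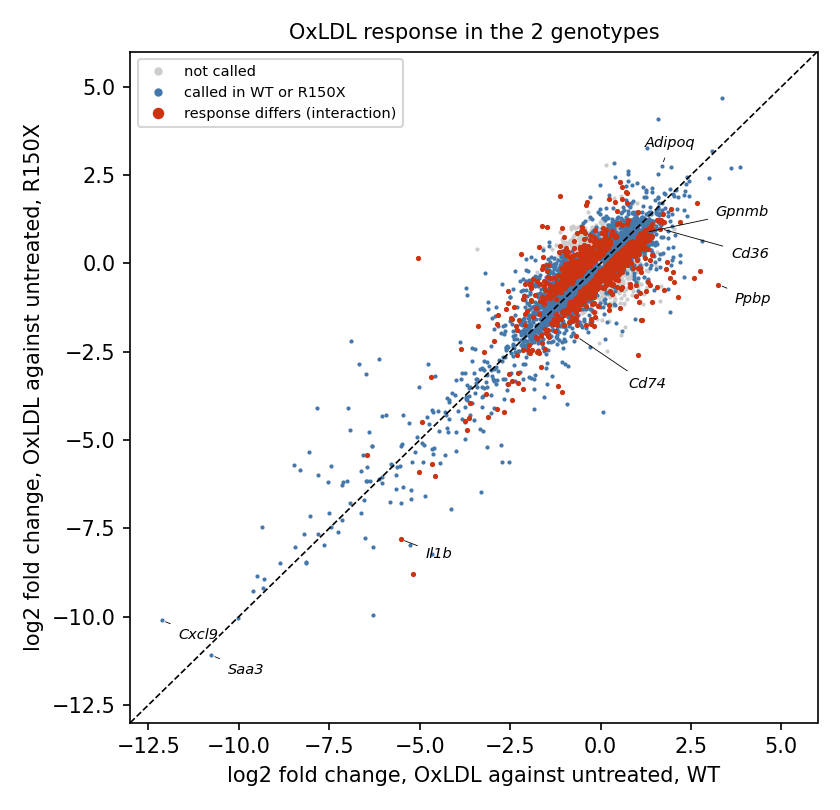
Log2 fold change with OxLDL in WT (horizontal axis) against R150X (vertical axis), 1 point per tested gene; grey, not called; blue, called in at least 1 genotype; red, response differs between genotypes. The dashed line marks equal responses, the genes called in at least 1 genotype have a slope of 0.963 around it, and Ppbp, Il1b and Cd74 are among the 1276 red genes.

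The interaction asked which OxLDL responses depend on genotype. Lipid, lysosome, antioxidant, antigen presentation and macrophage genes responded less positively or more negatively in R150X, and ATF4 targets more positively. This partly restates the difference between untreated genotypes. Cd36 increased less in R150X, by a log2 difference of -0.66 (SE 0.0652, adjusted p = 1.58e-06), but still ended above WT. Lpl was at -0.48 and Plin2 at -0.51. Il1b differed by -2.28 and Cd74 by -1.39. The ATF4 targets Asns and Trib3 differed by 0.88 and 1.15.

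In the interaction, a member counted as higher or lower is one whose OxLDL response was called more positive or more negative in R150X than in WT. By that count, NRF2 genes were lower in 17 of 23 cases and higher in 0 (1 higher without WT_untreated replicate 3 or WT_OxLDL replicate 1, camera adjusted p = 1.95e-16), lysosomal genes lower in 15 of 38 and higher in 0 (adjusted p = 3.37e-10), and lipid-associated macrophage genes lower in 14 of 18 and higher in 0 (adjusted p = 3.04e-15). MHC class II was lower in 5 of 10 cases (adjusted p = 4.75e-19) and macrophage identity in 10 of 15 (adjusted p = 1.95e-11). PPAR genes were lower in 9 of 20 cases and higher in 2 (1 without WT_untreated replicate 1, adjusted p = 1.74e-05). Adhesion genes were lower in 9 of 26 and higher in 1 (0 without WT_untreated or WT_OxLDL replicate 1 or R150X_OxLDL replicate 3, 2 without any R150X_untreated replicate, adjusted p = 5.13e-06). LXR targets were lower in 6 of 13 cases and higher in 1 (adjusted p = 0.00219), with Abcg1 at -0.38 and Scd1 at 1.21. Cytokine genes were lower in 6 of 26 cases and higher in 1 (adjusted p = 0.00219). Cholesterol biosynthesis genes were lower in 4 of 24 (1 without WT_untreated replicate 2 or R150X_OxLDL replicate 1, 2 without WT_untreated replicate 1, WT_OxLDL replicate 1 or 2 or R150X_OxLDL replicate 2) and higher in 0 (adjusted p = 0.00142). Beta-oxidation genes were lower in 3 of 18 (1 without WT_untreated replicate 3, WT_OxLDL replicate 2 or R150X_OxLDL replicate 2 or 3) and higher in 0 (adjusted p = 0.000163). Scavenger genes were lower in 3 of 15 cases and higher in 1 (0 without any library other than WT_OxLDL replicate 3 and the R150X_untreated ones, adjusted p = 0.0282, and adjusted p = 0.0709 with an estimated correlation). This call was lost without WT_untreated replicate 3, WT_OxLDL replicate 3, R150X_untreated replicate 2 or 3, or R150X_OxLDL replicate 1 or 3 (adjusted p of 0.0543 to 0.0986). ATF4 targets were higher in 11 of 21 cases and lower in 2 (1 without WT_untreated replicate 1 or WT_OxLDL replicate 3, adjusted p = 5.08e-10).

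No list call was made in the interaction for interferon genes (adjusted p = 0.783), with Gbp2 at -0.75, or for alternative activation (adjusted p = 0.669, median -0.09 but mean 0.17), ER chaperones (adjusted p = 0.558), glycolysis (adjusted p = 0.669) or the cell cycle (adjusted p = 0.669). Neutrophil markers were lower in 7 of 12 cases (4 without R150X_OxLDL replicate 3) and higher in 0 (adjusted p = 4.28e-07), and stromal markers higher in 8 of 12 and lower in 1 (0 without any library other than WT_untreated replicate 1 and R150X_untreated replicate 3, adjusted p = 3.51e-08). Osteoclast markers were lower in 2 of 6 cases (adjusted p = 0.0698), B cell markers higher in 1 and lower in 1 of 4 (adjusted p = 0.845), and the Y-linked list with Xist higher in 1 of 5 (adjusted p = 0.278, median -0.03 but mean 0.99). Of 12 mitochondrial mRNAs, 1 was lower (7 without WT_OxLDL replicate 3, 2 without R150X_OxLDL replicate 1, 0 without WT_untreated replicate 3, WT_OxLDL replicate 1, R150X_untreated replicate 2 or R150X_OxLDL replicate 2 or 3, adjusted p = 0.00624, and adjusted p = 0.474 with an estimated correlation). No dendritic, T and NK or mast cell marker (each adjusted p = 0.845) and no erythroid marker passed the edgeR test.

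The interaction test of edgeR called 1276 genes, 480 more positive and 796 more negative in R150X, with 63 in each direction at a difference of 2-fold or more. Scaled by library size alone, 66.5% of 1320 calls were more positive, against 37.6% with TMM, so the balance of directions turned with scaling. Under that scaling the lysosome had 1 higher and 9 lower members, glycolysis 3 higher and 0 lower, cholesterol biosynthesis 2 lower and beta-oxidation 1, and the scavenger list call was lost (adjusted p = 0.0506). The medians of scavenger (-0.05), alternative activation (-0.09), ER chaperone (-0.06), osteoclast (-0.09), dendritic (-0.07) and Y-linked genes with Xist (-0.03) turned to 0.04, 0.0064, 0.04, 0.0038, 0.02 and 0.06. Without replicate 1 of the untreated R150X group, 1246 genes were called. Adjusted over the list alone, counts moved for LXR targets (9 lower), cholesterol biosynthesis (5), scavenger (4), PPAR (11), beta-oxidation (4), NRF2 (1 higher, 18 lower), the lysosome (22 lower), cytokines (9 lower), alternative activation (3 higher, 2 lower), lipid-associated genes (1 higher), ATF4 (12 higher), ER chaperones (0 higher), adhesion (2 higher, 11 lower), MHC class II (7 lower), macrophage identity (12 lower), stromal (2 lower), osteoclast (3 lower), erythroid (1 lower) and mitochondrial (2 lower).

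**Figure D4:**
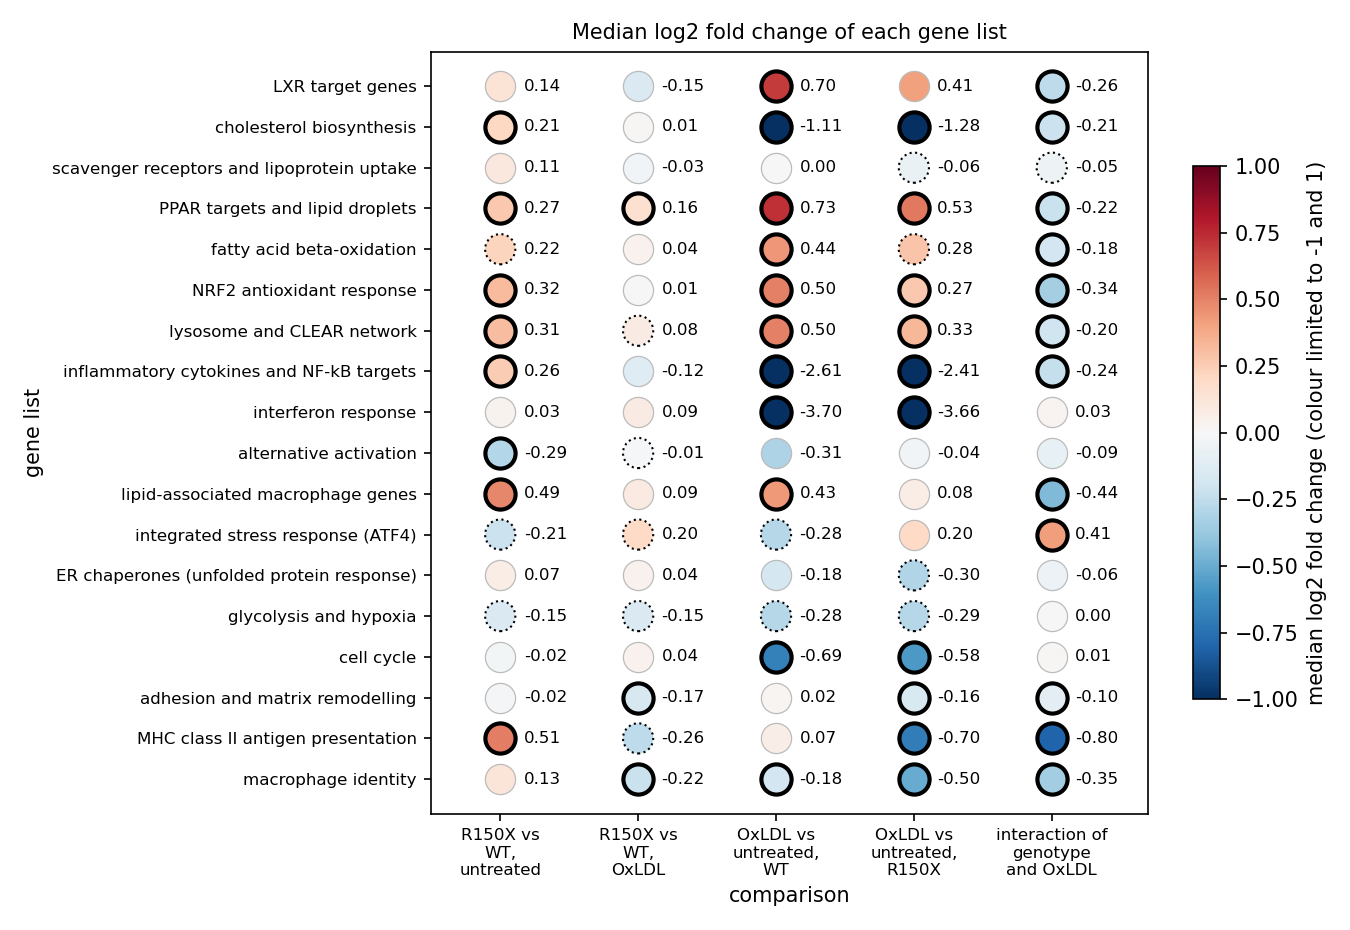
Median log2 fold change (colour and printed value) of the 18 pathway lists (vertical axis) in the 5 comparisons (horizontal axis); a solid black ring marks lists called by camera with both the preset and the estimated correlation, a dotted ring lists called with the preset only, and a thin grey ring lists not called. Interferon genes have the lowest medians, -3.70 and -3.66 with OxLDL, and NRF2 genes have a median of 0.32 between untreated genotypes and 0.01 with OxLDL.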

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

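Of the tests in this part, the one for a swap of libraries and the scaling by library size alone were chosen only after the result was seen, and the 4 genes escaping X inactivation after Xist but before their own values. Each value below is the log2 response to OxLDL in R150X minus that in WT, and each stands here because edgeR's interaction test found the response to differ between the genotypes (genes) or because camera did (lists). The test called 1276 genes. Among 100 splits of the libraries, which exchange libraries between the genotypes within each treatment, 6 called as many genes, the real one included. The 5 others kept the untreated groups whole and exchanged 2 or 3 of the 3 OxLDL-treated libraries, and the highest called 5118. Such a split carries the genotype difference itself into the interaction, so these counts do not measure chance. Chance is therefore neither excluded nor favoured by this test. Of the other splits, 75 called 0 genes, and the highest that exchanged an untreated library called 166.

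MHC class II genes had a median of -0.80 and macrophage identity genes one of -0.35. H2-Eb1 was at -1.45, Cd74 at -1.39 and H2-Aa at -1.33, and the macrophage genes Cd14, Csf1r and Lyz2 were at -0.63, -0.50 and -0.38. Lipid-associated macrophage genes had a median of -0.44, with the lectin Clec7a at -0.69, Cd9 at -0.51 and Spp1 at -0.45. Lists of lipid handling had medians of -0.22 for PPAR targets, -0.26 for LXR targets, -0.0500 for scavenger receptors (0.0415 scaled by library size alone), -0.18 for beta-oxidation and -0.21 for cholesterol biosynthesis. Plin2 was at -0.51, Fabp5 at -0.48, Lpl at -0.48, Cd36 at -0.66, Cxcl16 at -0.84, Cd68 at -0.22, Abcg1 at -0.38, Mylip at -0.45, the desaturase Scd1 at 1.21, Ucp2 at -0.46, Etfa at -0.29, Cpt1a at -0.29, Cyp51 at -0.39, Pmvk at -0.77 and Mvd at -0.40. NRF2 genes (median -0.34) and lysosomal genes (median -0.20) included Prdx1 at -0.71, Gsr at -0.70, Taldo1 at -0.59, Ctss at -0.65, Atp6v1b2 at -0.45 and Psap at -0.42.

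Inflammatory genes had a median of -0.24, with Il1b at -2.28, Icam1 at -0.47 and the antagonist Il1rn at 0.48. Interferon genes included Gbp2 at -0.75, Ifi47 at -0.46 and Ifit3 at 1.03, whose near-identical copy can share its reads. ATF4 targets had a median of 0.41, with Trib3 at 1.15, Asns at 0.88 and Atf3 at -0.53. Adhesion genes had a median of -0.10, with the proteases Mmp9 at -1.30, Mmp13 at -0.72 and Mmp12 at -0.61. Single members of lists without a call were Klf4 at 0.57, Mrc1 at 0.34, Tgfb1 at -0.27, Sel1l at 0.22, Vegfa at 0.40, Pkm at -0.20, Mki67 at 0.61 and Pcna at -0.39. Markers of other cells were Lcn2 at -1.04, S100a8 at -0.76 and Ngp at -0.73 for neutrophils, Cxcl12 at 0.64, Col3a1 at 0.48 and Sparc at 0.38 for stroma, Blnk at -0.55 and Ebf1 at 0.66 for B cells, and Dcstamp at -1.38 and Atp6v0d2 at -0.43 for osteoclasts. The mitochondrial gene mt-Nd3 was at -1.18.

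Of the genes named for the size of the difference, the lower ones included the platelet genes Ppbp at -3.86 and Itga2b at -2.22, Tarm1 at -3.62 (a value that rests on 1 count in OxLDL-treated R150X cells and depends on the prior count), Rps27a at -1.93 and Mcemp1 at -1.54. Rps27a varied widely between libraries, at 169 ± 122 CPM (SD, n = 3) in OxLDL-treated WT cells, and with DESeq2 its call was lost (adjusted p = 0.086). The higher ones were G0s2 at 1.78, Atp6v0e2 at 1.75, Sez6l2 at 1.63, Adamts15 at 1.58 and Epb41l4b at 1.56. Xist was at 5.19 and Gpnmb itself at -0.36.

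Leaving out 1 library ended some of these calls. For G0s2 it was WT_untreated replicate 1 (adjusted p = 0.0729), for Rps27a WT_OxLDL replicate 3 (0.0636), for Ifit3 WT_OxLDL replicate 3 and R150X_OxLDL replicate 1 (up to 0.0709), and for Epb41l4b WT_untreated replicate 1, WT_OxLDL replicate 2 and R150X_untreated replicate 3 (up to 0.149). For Atp6v0e2 it was WT_untreated replicates 2 and 3 and WT_OxLDL replicates 1 and 2 (up to 0.17), and for Tarm1 each WT_untreated replicate, WT_OxLDL replicates 1 and 2 and R150X_OxLDL replicates 1 and 2 (up to 0.241). For Etfa it was WT_untreated replicate 3, WT_OxLDL replicate 2 and R150X_OxLDL replicates 2 and 3 (up to 0.0798), and for Pkm each WT_untreated replicate, WT_OxLDL replicate 3 and R150X_OxLDL replicates 1 and 2 (up to 0.0865). Mvd lost its call without WT_untreated replicate 2, WT_OxLDL replicates 2 and 3, R150X_untreated replicate 1 and R150X_OxLDL replicates 1 and 2 (up to 0.0768). Pmvk lost it without WT_untreated replicates 1 and 2, WT_OxLDL replicates 1 and 3, R150X_untreated replicate 1 and R150X_OxLDL replicates 1 and 2 (up to 0.0841), and Tgfb1 without WT_untreated replicates 1 and 2, WT_OxLDL replicate 3, R150X_untreated replicate 1 and each R150X_OxLDL replicate (up to 0.119). The call of mt-Nd3 ended without WT_untreated replicate 3, WT_OxLDL replicates 1 and 3, R150X_untreated replicates 1 and 2 and R150X_OxLDL replicates 2 and 3 (up to 0.0786). Cpt1a lost it without each library other than WT_OxLDL replicate 3 and R150X_untreated replicate 1 (up to 0.106), and Sel1l without each library other than the R150X_untreated ones (up to 0.115). Scaled by library size alone, the calls of Mvd, Cd68, Etfa, Cpt1a, Tgfb1 and Pkm were lost, at adjusted p of 0.0887, 0.149, 0.128, 0.176, 0.18 and 0.238, and with no filter that of Etfa (0.0761). The list call for scavenger receptors was lost by library size alone (adjusted p = 0.0506), at adjusted p = 0.0709 with an estimated correlation, and without 6 single libraries named earlier (up to 0.0986).

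Xist was higher and Y-linked genes lower in R150X than in WT, and since the OxLDL-treated WT libraries held 0, 1 and 1 Xist counts, the value of 5.19 depends on the prior count. A swap of libraries between the genotypes was argued against by Gpnmb, since the lowest level in a WT library was at least 12.9 times the highest in an R150X library of the same treatment. A candidate explanation is that the R150X libraries hold cells of both sexes, which would raise genes that escape X inactivation. The lower of the 2 median log2 fold changes of 4 such genes was 0.0341, and 1 of the 4, Eif2s3x, was called, at 0.22 (adjusted p = 0.00289) untreated and 0.20 (adjusted p = 0.0136, and up to 0.0804 without WT_OxLDL replicate 1 or R150X_OxLDL replicate 2) with OxLDL. Xist with Y-linked genes at 55.9% to 73.1% of WT in R150X goes with a mixture. The median (-0.0415 by library size alone) cannot decide, as a mixture may raise it little. The mice's sex stays open.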

How the results depend on the processing

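Depth and group size set the limits of these results. Genes near the floor of 3 counts, 0.158 to 0.209 CPM, cannot be compared. Scaling by library size alone and the exclusion of chromosomes X and Y were added after the data had been seen, and the other alternatives were planned. Under 1278 alternative values for 90 list results, 1225 kept their side of the threshold, 27 lost the call, 26 gained it and 0 reversed. Under 5604 alternative values for 403 named-gene results, 5451 kept the call, 153 lost it (133 of them on leaving out 1 library) and 0 reversed, and 36 results lost it under at least 1 alternative. The cause was not tested for calls lost on leaving out a library, which also leaves fewer samples.

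The number of genes called depended most on a minimum fold. With a log2 fold change of at least 1 it was 484 for the genotypes untreated, 362 with OxLDL, 1455 for OxLDL in WT, 1161 in R150X and 126 for the interaction, against 5056, 1996, 7025, 5983 and 1276, by construction. In the same order the counts were 4421, 1808, 6271, 5311 and 1247 with DESeq2, 5037, 1998, 6982, 5984 and 1246 with DESeq2's size factors in edgeR, 4922, 2168, 6917, 5881 and 1512 with no filter, 5036, 2006, 6883, 5911 and 1290 with the stricter filter (14073 genes), 5097, 2108, 6997, 6003 and 1353 with a robust dispersion, and 5120, 2034, 7102, 5919 and 1320 by library size alone. Fits to only the groups compared gave 4517, 2169, 7442 and 5253 for the comparisons other than the interaction. Without genes near Gpnmb 4963 and 1959 genes were called between genotypes, and without chromosomes X and Y the interaction called 1237. Leaving out 1 library gave 3878 to 4838, 1426 to 1832, 6065 to 6301, 5024 to 5866 and 893 to 1392 genes, and 10 to 11, 8 to 9, 13, 14 to 15 and 12 to 13 lists called of 18, against 11, 8, 13, 14 and 13.

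With an estimated correlation, 3 lists were called between genotypes with OxLDL, against 8 with the preset one, and 8, 11, 10 and 12 in the other comparisons; fry, which does not compare a list with other genes, gave 16, 12, 17, 17 and 13. The odds ratio of calls near Gpnmb in untreated cells, 1.37, was 1.08 with DESeq2 (Fisher's exact p = 0.546), 1.28 within 10 Mb (exact p = 0.164), 1.16 within 50 Mb (exact p = 0.128) and 1.14 to 1.41 on leaving out 1 library (exact p from 0.0514 to 0.37 without each of these libraries other than WT_untreated replicate 2, without which it was 0.0257), and among genes at least 2-fold different 2.36 (exact p = 0.00432). With OxLDL it was 1.65 within 10 Mb (exact p = 0.0269) and 1.33 within 50 Mb (exact p = 0.0238), against 1.36, and the cause was not tested. The slope of the OxLDL responses was 0.928 over genes called in WT, 1.03 over genes called in R150X and 0.919 to 0.981 on leaving out 1 library. The labels number the replicates 1 to 3 in each group, but deviations of same-numbered libraries from their group means correlated above 0.1 in 4 of 12 pairs and best with their own number in 5 of 12 (r from -0.15 to 0.31 over 9156 genes), so the numbers were not taken to pair libraries. With the replicate block, 5355, 2164, 7190, 6209 and 1491 genes and 11, 9, 13, 14 and 13 lists were called, with odds ratios of 1.33 and 1.19 near Gpnmb.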

Other observations

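Of the gene lists of this part, 6 with the genes named from them, and the tests of scaling and of stromal cells were chosen only after the result was seen, as was the check of the window that holds Gpnmb, and the genes escaping X inactivation were chosen after Xist but before their own values. The platelet and adipocyte lists were built around Ppbp and Itga2b and around Plin1, Adipoq and Car3, which already stood out, so tests of these lists would restate those genes and only their members are given. With OxLDL in WT, 8 of 10 platelet and megakaryocyte genes rose and 0 fell, with the chemokine Ppbp at a log2 fold change of 3.26 and the integrin Itga2b at 1.56. In R150X, 4 fell and 2 rose (1 without R150X_untreated replicate 1 or 3 or R150X_OxLDL replicate 1 or 2), with Ppbp at -0.60, Itga2b at -0.66 and the platelet factor Pf4 at -0.69. In the interaction 6 members were lower and 1, Itgb3, higher (0 higher without WT_untreated or WT_OxLDL replicate 1 or R150X_OxLDL replicate 3). Between untreated genotypes 5 members rose and 0 fell in R150X (3 rose without WT_untreated replicate 2 or R150X_untreated replicate 2). With OxLDL 1 rose and 5 fell (3 fell without WT_OxLDL replicate 2 or R150X_OxLDL replicate 3). The integrin Itgb3, which osteoclasts also express, rose in both, by 0.98 and 1.39. Of 5 adipocyte markers, 4 rose in untreated R150X cells and 3 in R150X with OxLDL. With OxLDL 4 rose in R150X and 3 in WT, and 1 fell in each (0 in R150X without R150X_OxLDL replicate 2, and 0 in WT without WT_untreated replicate 2 or 3 or WT_OxLDL replicate 1 or 2). Adipoq, Plin1 and Car3 were at 2.25, 2.25 and 2.76 between untreated genotypes, and Fabp4, which macrophages also express, at 0.59.

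Genes of the basal machinery of the cell were higher in untreated R150X cells. Of 77 nuclear-encoded respiratory chain genes 63 rose and 0 fell (camera adjusted p = 3.6e-12). Of 81 ribosomal protein genes, many of which have processed pseudogenes that can share reads, 51 rose and 1 fell (adjusted p = 1.59e-07), and of 38 proteasome genes 30 rose and 0 fell (adjusted p = 1.59e-07). None of these list calls held with an estimated correlation (adjusted p = 0.269, 0.437 and 0.269), and scaled by library size alone 51, 31 and 15 members rose. Between the OxLDL-treated genotypes 3, 3 and 2 rose (1 each without R150X_OxLDL replicate 3, WT_OxLDL replicate 1 and WT_OxLDL replicate 2 in turn, and 3, 9 and 4 without R150X_untreated replicate 1), with no list call (adjusted p = 0.0559, 0.177 and 0.0559). All 3 lists were called without WT_OxLDL replicate 1 (adjusted p = 0.016, 0.0356 and 0.0149), and 1 or 2 without R150X_untreated replicate 1 or 2 or R150X_OxLDL replicate 1 or 3 (adjusted p of 0.00587 to 0.0483). In the interaction 11, 2 and 3 were lower (from 5, 1 and 1 without WT_untreated replicate 2 to 19, 13 and 8 without R150X_untreated replicate 2), with list calls (adjusted p = 1.51e-11, 2.56e-07 and 7.79e-06) that were lost with an estimated correlation (adjusted p = 0.337, 0.445 and 0.387). Proteasome genes fell with OxLDL in 32 of 38 cases and rose in 2 in R150X (adjusted p = 1.27e-05, and adjusted p = 0.768 with an estimated correlation) and fell in 25 and rose in 3 in WT (adjusted p = 0.0418, and adjusted p = 0.743 with an estimated correlation). Without WT_untreated replicate 1 or WT_OxLDL replicate 2, 16 and 17 fell in WT and the call was lost (adjusted p = 0.0617 and 0.0512). Transfer RNA synthetases rose in 8 of 20 cases in R150X with OxLDL (5 without WT_OxLDL replicate 2, adjusted p = 0.000164, and adjusted p = 0.0783 with an estimated correlation). Their responses to OxLDL were more positive in R150X in 8 of 20 cases and more negative in 0 (adjusted p = 1.42e-05, and adjusted p = 0.0863 with an estimated correlation). Genes escaping X inactivation were not called as a list (adjusted p = 0.645 untreated and 0.177 with OxLDL).

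Many genes separated the genotypes, and DBA/2 ancestry is a candidate explanation. Within 20 Mb of Gpnmb lay 1.70% of genes called untreated and 1.80% with OxLDL. With 214 tested genes there, both shares had to be small and cannot test a linked DBA/2 segment. Of the 154 genes that differed at least 2-fold in the same direction in both treatments, 0% lay in windows of 10 Mb with an excess of them, of 281 windows tested. The window that holds Gpnmb, with 3 of these genes, did not pass either (Fisher's exact p = 0.0234, adjusted p = 1), so the test may miss such segments. Segments near Gpnmb or elsewhere, their distant effects, the sex markers, a different cell mix (neutrophil and stromal markers) and the R150X allele stay open. None was tested apart from the others. The 10 splits of 3 libraries against 3 are too few for a share under 0.05; the real split called 5056 genes untreated and 1996 with OxLDL, and the highest other 1 and 0.

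Interferon and inflammatory genes fell with OxLDL in both genotypes, with the lowest medians of the 18 pathway lists in each. Library size alone moved genes slightly down (median -0.11 in WT, -0.02 in R150X). That 98.3% of the 58 members were called lower in each genotype thus cannot test scaling. A loss of stromal cells was argued against. In R150X the median of the stromal markers, -0.67, lay 2.61 above that of the 58 members, -3.27 (interquartile range of the markers 0.570). In WT it lay 2.26 above (range 1.15). OxLDL itself may be the cause, as may a difference in handling or in culture conditions between treated and untreated cells, which the labels do not exclude and which was not tested. For these comparisons, too, 10 splits are too few for a share under 0.05; the real split called 7025 genes in WT and 5983 in R150X, and the highest other 0 in each.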
